A study of Mus musculus with 9 samples.

How the data were processed

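RNA from sorted mouse muscle cells was measured on 9 single-colour Agilent whole mouse genome arrays, 3 in each of 3 groups. Per the labels' protocols, 1500 cells from 3 mice per line, in 3 independent experiments, were sorted into lysis buffer, their RNA was amplified as cDNA with the SuperAmp method, and the cDNA was labelled with Cy3. Groups and replicate numbers were taken from the sample titles and source names. The labels give the cell type of the re-isolated samples as mononucleated cells and that of the others as satellite cells. They do not give the gate of the sort.

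The scanner tables held 45018 spots per array, of which 1639 were control spots. Their intensity values had been made with Agilent Feature Extraction 10.5.1.1, per the file headers, which record a spatial and multiplicative detrending and a background subtraction before the processed signal was written. A spot counted as well above background when it passed that software's own flag, which the headers set at 13 standard deviations of the background. The deposited value table held log2 values of 31918 spots that the authors had kept. The submitters' processing notes name limma for it, with no version or step. Its columns correlated with the log2 mean signal of the same array at r between 0.9875 and 0.9993, and its column medians were 7.704, 7.709, 7.68, 7.69, 7.701, 7.669, 7.676, 7.633 and 7.656 in the order iPax3 replicates 1 to 3, iPax7 replicates 1 to 3 and satellite replicates 1 to 3. That shows an uncentred log2 scale with columns adjusted to each other. The method of that adjustment and the reason for the choice of spots stay unknown, so the table served only as an alternative. All 9 of its columns were used.

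For the values given here, the processed signal was taken as log2 after values under the smallest positive signal of an array were set to it, and the 75th percentile over the non-control spots was subtracted from each array. Spots that the software flagged as outliers were left out, between 60 and 342 per array. No spot was saturated. Spots of the same probe were averaged, and probes were kept when well above background on at least 3 of the 9 arrays, which left 32985 of 41174 probes. A probe also needed values on all but 2 arrays and on at least 2 arrays of each group. In all, 16672 probes were well above background on all 9 arrays. Of all probes, 24375 were named through their accession, 6301 carried a current symbol and 2426 were renamed from an older symbol with the reference gene table, and 8072 kept the name in the file. The probe with the highest mean over all arrays stood for its gene, which gave 22705 genes, 22563 of them with a value on every array.

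Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust options) in a single fit with a mean for each group over all 9 arrays and no replicate block, at a Benjamini-Hochberg adjusted p of 0.05. The fit had 6 residual and 3.2 prior degrees of freedom. Values after the sign ± are standard errors of the fit for differences and standard deviations for group means. Every count of called genes was the same when an absolute log2 difference of at least 1 was also asked. Array counts beside a gene are those of the probe that stands for it, unless any probe is named. A probe that was not well above background on any array of a group has only a bound there. Its difference is given as at least N-fold, the mean of the brighter group against the mean of the dimmer group with each array of the latter raised to the lowest signal that was well above background on it. Such a bound holds for the background subtraction, scaling and probe used here. Under the alternatives a difference could be smaller than its bound. The number of arrays limits the precision: in simulated data with known changes, over the 22705 genes, the test recovered 0% of changes of 2 log2 units, 12% of changes of 4 and 56% of changes of 8 for iPax3 against satellite cells, with 1 false call. For iPax7 against satellite cells these shares were 0%, 18% and 60%, with 4 false calls, and for both groups together 2%, 28% and 70%, with 5 false calls. Of 35 simulated lists, the list shifted by 2 log2 units had a camera adjusted p of 5.44e-10 and 0 of the others passed. The simulated genes were drawn independently of each other, whereas the estimated correlation of the ribosomal list, for one, was 0.421. The simulation therefore does not show how often correlated lists pass by chance.

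The comparisons, the test, the alternatives and 36 gene lists were set before the data were examined. The lists cover markers of satellite cell quiescence, myogenic determination, differentiation and fusion, adult fibres, developmental sarcomere isoforms, the fetal switch, oncofetal genes, Notch, cell cycle genes and their inhibitors, immediate early genes, fibrillar matrix, basement membrane, integrins and adhesion, MHC class I, interferon response, Hox genes, regional identity, imprinted genes, pluripotency, immune, endothelial, fibroblast, pericyte and smooth muscle, Schwann and neural, erythroid, adipogenic and cartilage or bone cells, sex-linked genes, respiratory chain, glycolysis and hypoxia, ribosomal proteins, unfolded protein response, Wnt, TGF-beta and BMP, and the dystrophin complex. The 35 lists with at least 5 measured genes were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. The sex-linked list had 3 measured genes and was not tested. Pax3 and Pax7 were always named. For each pairwise comparison the rule also took the 10 largest rises and 10 largest falls among called genes with proper symbols whose groups did not overlap and that were above background on all 3 arrays of the higher group, and up to 4 members of each list with the smallest p. Not every gene that the rule took is named in the text.

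The alternatives were normexp background correction with an offset of 50, quantile normalisation, median centring, the deposited value table, other filters on dim probes, the mean of a gene's probes, a fit on the compared groups alone, trend and robust moderation, array weights, the replicate number, the slide and the scan day as blocks, an estimated correlation for lists, and leaving out each array. For a random block, camera was run on values and a design transformed with the estimated block correlation, as lmFit does. Raising low values to the detection floor was added after the data were seen. The arrays lay on 5 slides and were scanned on 3 days. The 3 iPax3 arrays and iPax7 replicate 1 shared slide 1, iPax7 replicates 2 and 3 shared slide 2, and the satellite arrays each had a slide of their own. All re-isolated arrays were scanned on day 1, satellite replicate 1 on day 2 and satellite replicates 2 and 3 on day 3. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.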

Results

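The data were whole-genome RNA levels from 9 arrays of cells taken from the tibialis anterior muscle of 3-month-old mice. In 6 samples, myogenic progenitors made from pluripotent stem cells had been transplanted into the muscle and were re-isolated from it as mononucleated cells. The iPax3 and iPax7 lines, named after the paired-box transcription factors Pax3 and Pax7, gave 3 arrays each. The other 3 arrays held adult satellite cells, the resident stem cells of skeletal muscle. The host strain of the re-isolated cells was NSG/NSGmdx4cv and that of the satellite cells Pax7-ZsGreen, so that strain, slide and scan day all differed between re-isolated and satellite cells. The labels say that the cells came from 3 independent experiments. The p-values measure the spread between these samples and treat the arrays as independent of each other. The iPax3 arrays all shared a slide, so their spread is a spread within that slide. The estimated correlation between arrays of the same slide, used for the random block, was 0.431. With the slide as a random block, fewer genes were called in each comparison with satellite cells, as given below.

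The share of probes well above background was 71.3%, 77.3% and 69.2% in iPax3 replicates 1 to 3, 56.6%, 68.4% and 73.2% in the iPax7 replicates, and 79.7%, 57% and 60.4% in the satellite replicates. Gene levels of iPax3 and iPax7 arrays correlated across genes at a mean Pearson r of 0.7, against 0.61 between iPax3 and satellite arrays and 0.6 between iPax7 and satellite arrays. Genes are not independent replicates, and these are descriptions. Within groups the mean r was 0.73 for iPax3, 0.68 for iPax7 and 0.64 for satellite cells. Satellite replicate 1 correlated with the re-isolated arrays at a mean r of 0.67, and satellite replicates 2 and 3 at 0.58 and 0.57. The distance between group means was 203 log2 units over all genes between iPax3 and iPax7, 277 between iPax3 and satellite cells and 275 between iPax7 and satellite cells.

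**Figure D1:**
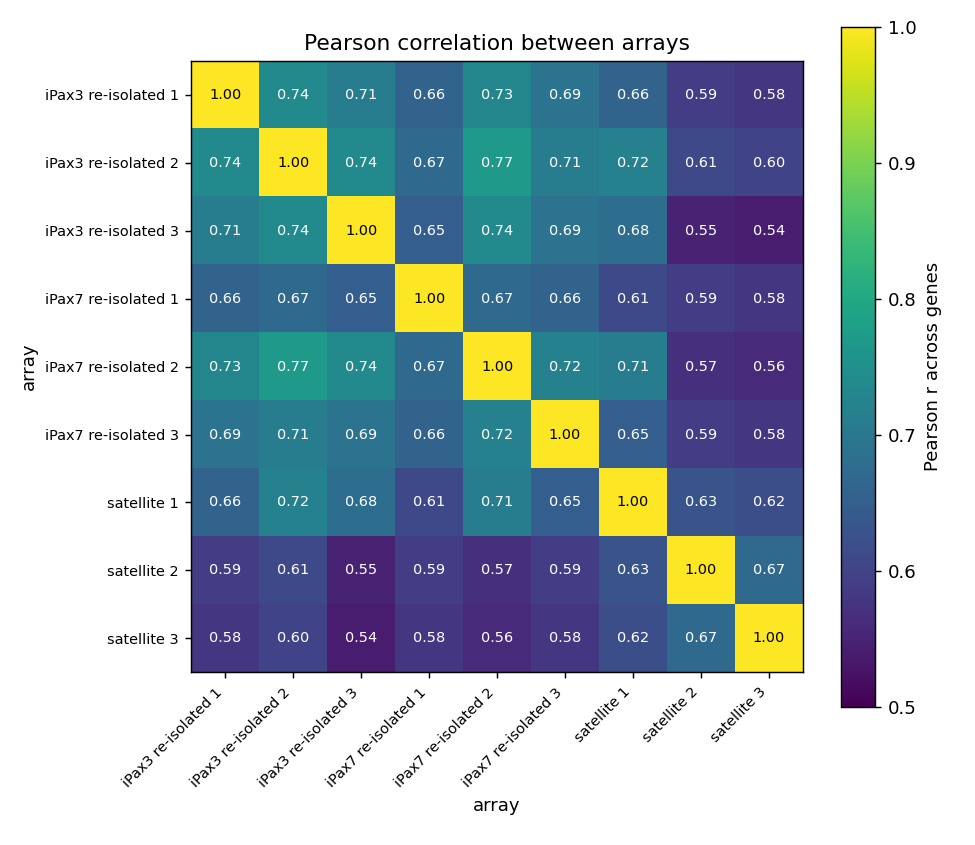
Pearson correlation across genes between each pair of the 9 arrays (both axes: arrays, colour and printed value: r). The iPax3 and iPax7 arrays had a mean r of 0.7 with each other, and satellite replicate 1 had a mean r of 0.67 with the re-isolated arrays, against 0.58 and 0.57 for satellite replicates 2 and 3.

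Pax7, the transcription factor that marks satellite cells, had a mean level of 1.92 ± 2.26 (SD, n = 3, log2 relative to the 75th percentile of the array) in satellite cells, −2.4 ± 1.63 in iPax3 cells and −3.64 ± 0.34 in iPax7 cells. The 3 satellite arrays read 2.89, 3.53 and −0.66, the iPax3 arrays −3.15, −0.53 and −3.52, and the iPax7 arrays −3.9, −3.25 and −3.76. The difference from satellite cells did not pass the test in iPax3 (log2 −4.32 ± 1.21, adjusted p = 0.196) or iPax7 cells (−5.56 ± 1.21, adjusted p = 0.108), nor in both groups combined (−4.94 ± 1.05, adjusted p = 0.0722). Pax3 was measured above background on 2 of 3 arrays in each group, with means of −4.44 ± 0.51, −3.98 ± 1.19 and −3.13 ± 2.16 in iPax3, iPax7 and satellite cells. Its array values were −4.36, −4.98 and −3.98 in iPax3 cells, −2.93, −5.28 and −3.72 in iPax7 cells and −4.45, −4.29 and −0.64 in satellite cells. Its difference from satellite cells was −1.31 ± 1.12 (adjusted p = 0.632) in iPax3 and −0.85 ± 1.12 (adjusted p = 0.788) in iPax7 cells. Whether the array probes can tell a transgene from the endogenous gene was not examined, so these values do not check which line a sample came from.

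The first question was how iPax3 cells re-isolated from muscle differed from adult satellite cells. Extracellular matrix genes were far higher in the iPax3 cells, and single genes of secreted regulators moved both ways. Fst, which encodes the activin and myostatin binding protein follistatin, rose at least 419-fold, to 3.53 ± 0.17 (SD, n = 3; adjusted p = 0.00131), and the Wnt modulator Dkk2 rose at least 207-fold, to 2.51 ± 0.88 (adjusted p = 0.00261). Over the alternatives, the rises of Fst and Dkk2 in iPax3 cells were as small as 6.01 and 4.98 log2 units. The matrix proteoglycan gene Dcn rose by 8.59 ± 0.75 log2 units (adjusted p = 0.00255), from −1.19 ± 0.89 in satellite cells to 7.4 ± 0.58 in iPax3 cells (SD, n = 3). The BMP antagonist gene Chrdl2, known from quiescent satellite cells, fell by 9.2 on the log2 scale (adjusted p = 0.00204).

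Among the other largest rises in iPax3 cells were Bmp5, which encodes a BMP ligand (9.65 ± 0.76, its probe above background on 1 satellite array), the secreted Wnt antagonist gene Sfrp1 (9.24 ± 1.19, on 1 satellite array) and the matrix proteoglycan gene Aspn (at least 179-fold). With them rose the adhesion receptor gene Icam1 (8.73 ± 1.28, on 1 satellite array), Adamtsl3 (8.63 ± 0.69, on 1 satellite array), the membrane-bound protease gene Mmp16 (at least 85.2-fold) and the fibril-associated collagen gene Col14a1 (8.49 ± 0.73, on 2 satellite arrays). Their adjusted p lay between 0.00204 and 0.0343. Among the other largest falls were Hmgxb3 (at least 291-fold), the hormone gene Erfe (−7.82 ± 1.26, measured on 2 iPax3 arrays), the cation transporter gene Slc22a3 (at least 49.2-fold) and Ankrd1, which encodes an ankyrin repeat protein of striated muscle (−7.3 ± 1.13, on 2 iPax3 arrays). Next came the histone gene H4c4 (−6.38 ± 0.98), the transcription factor gene Sim2 (−5.99 ± 0.9, on 2 iPax3 arrays) and Cplx4 (−5.97 ± 0.81), with adjusted p between 0.0205 and 0.0424. The calls of Fst, Dkk2, Bmp5, Adamtsl3, Dcn, Col14a1 and Chrdl2 held whichever array was left out. Those of the other falls named held in 2 to 6 of 9 such fits, and those of Sfrp1, Aspn, Icam1 and Mmp16 in 3 to 7. Array counts here are those of the probe used. By any probe, Bmp5, Sfrp1, Icam1 and Adamtsl3 were above background on 3 satellite arrays and Mmp16 on 1. Over probes above background on all 9 arrays, where another probe stood for each of these genes, Icam1 differed by 0.54, Adamtsl3 by 1.86, Bmp5 by 2.69 and Sfrp1 by 5.52, and none was called. Of 15 alternatives 9 kept the call of Icam1, 11 that of Sfrp1 and 14 those of Adamtsl3 and Bmp5.

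Fibrillar matrix genes rose as a group in iPax3 cells: 21 of 23 were higher, with a median difference of 4.06, and 5 passed the test, among them Dcn, Postn (7.46 ± 0.75), Col1a1 (6.33 ± 0.75) and Col1a2 (6 ± 0.74). Adjusted over the list alone, 16 passed (camera adjusted p = 1.1e-17, and adjusted p = 0.0168 with an estimated correlation). Markers of fibro-adipogenic progenitors, fibroblasts and tenocytes moved with them, with 21 of 24 higher and a median of 3.22. Dcn, Pdgfra (7.79 ± 0.79), Col1a1 and Serpinf1 (4.34 ± 0.73) passed, and 14 passed adjusted over the list alone (camera adjusted p = 1.24e-12; adjusted p = 0.0168 with an estimated correlation). These lists share 4 genes. With 1 array left out, the calls of Dcn, Pdgfra and Postn held in 9 of 9 fits, those of Col1a1 and Col1a2 in 5 and that of Serpinf1 in 1. Basement membrane genes had a median of 2.08. Lama4 (7.71 ± 0.82), a laminin chain, and Col15a1 (5.14 ± 0.67) rose, 14 did not pass, and 6 passed over the list alone (camera adjusted p = 0.000106; adjusted p = 0.143 with an estimated correlation). The call of Lama4 held in 9 of 9 such fits and that of Col15a1 in 4. Imprinted genes had a median of 0.62 over 32 members, of which Dcn rose and Igf2 (9.58 ± 2.09, adjusted p = 0.107) and Dlk1 (4.26 ± 1.07, adjusted p = 0.153) did not pass; 3 passed over the list alone (camera adjusted p = 0.0195; adjusted p = 0.143 with an estimated correlation). Wnt genes had a median of 0.3, and of 27 members Dkk2 and Sfrp1, both known as secreted Wnt modulators, rose; 6 passed over the list alone (camera adjusted p = 0.0103; adjusted p = 0.278 with an estimated correlation).

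Markers of satellite cell quiescence had a median of −1.43 in iPax3 cells, beside the rise of the fibroblast markers by a median of 3.22. Of 27 members, Chrdl2 fell, Col15a1 rose and 25 did not pass, while 8 were lower and 3 higher adjusted over the list alone (camera adjusted p = 0.00476; adjusted p = 0.239 with an estimated correlation). Bmp6 (−3.8 ± 0.74, adjusted p = 0.0759) and Fgfr4 (−2.95 ± 0.66, adjusted p = 0.115) missed the threshold. Developmental sarcomere genes had a median of −0.72, with Ankrd1 lower, 14 members not passing and 2 lower over the list alone (camera adjusted p = 0.0288; adjusted p = 0.168 with an estimated correlation). Endothelial markers had a median of −1.15 with 0 of 20 called and 1 lower over the list alone (camera adjusted p = 0.0288; adjusted p = 0.168 with an estimated correlation). Lyve1 differed by −5.15 ± 1.24 (adjusted p = 0.14) and Cldn5 by −2.67 ± 0.85 (adjusted p = 0.26). Ribosomal protein genes had a median of −0.99 with 30 of 36 lower and 0 called, over all genes and over the list alone (camera adjusted p = 0.000446; adjusted p = 0.584 with an estimated correlation). This call was lost under quantile normalisation (adjusted p = 0.159) and in the deposited value table (adjusted p = 0.0703). Of 15 alternatives, 13 kept the calls of ribosomal genes and endothelial markers. Those of quiescence markers, developmental sarcomere and Wnt genes were each kept in 14. With satellite replicate 1 left out, the calls of quiescence markers (adjusted p = 0.22), developmental sarcomere (0.115), endothelial (0.398) and Wnt genes (0.0892, median −0.43) were lost. Leaving out iPax3 replicate 2 ended those of developmental sarcomere (0.0897), endothelial (0.0897) and ribosomal genes (0.0713), and iPax3 replicate 3 those of imprinted (0.0808) and Wnt genes (0.0808).

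In all, 98 of 22705 genes differed between iPax3 and satellite cells, 82 higher and 16 lower (83.7% higher), with a smallest called difference of 3.71 log2 units; 2823 genes had an unadjusted p under 0.05 against 1135 expected by chance. In 4283 genes (18.9%) the groups did not overlap, where chance gives 10%. The median over all genes was −0.186, so that changes are relative to the scaling of each array. With normexp background correction 112 genes were called and 67.9% of them were higher. The count was 25, 28 and 19 without iPax3 replicate 1, 2 or 3, 62 and 55 without iPax7 replicate 2 or 3, and 451, 31 and 43 without satellite replicate 1, 2 or 3. It was 14 with the slide and 27 with the scan day as a random block, and no slide or day held both re-isolated and satellite cells.

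**Figure D2:**
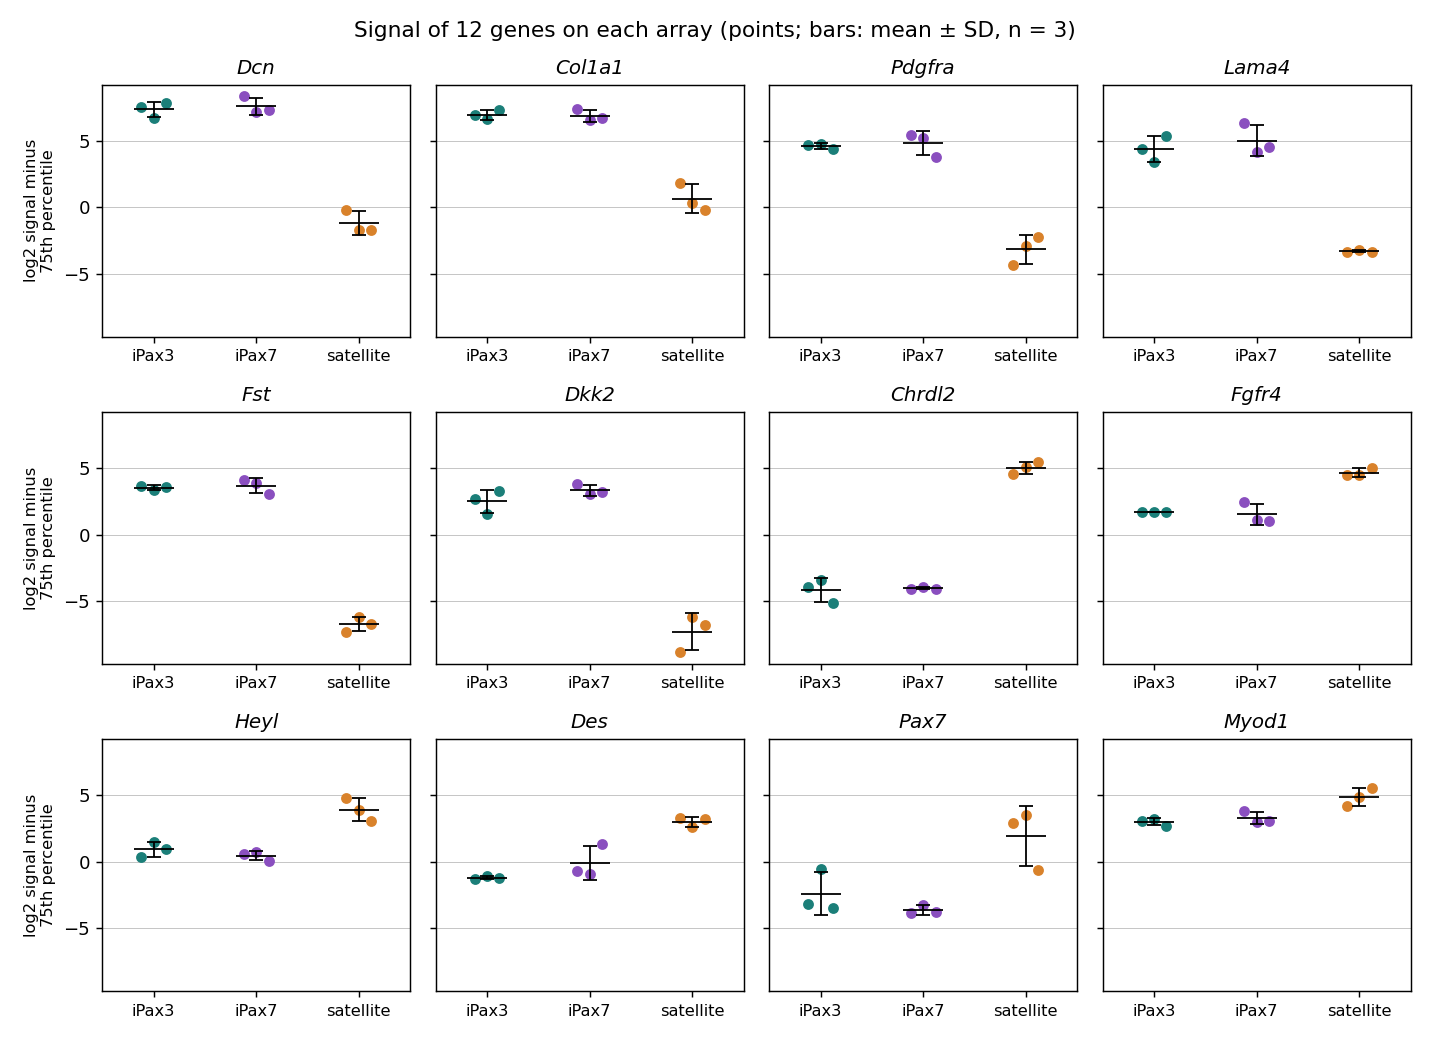
Levels of 12 genes on each array (vertical axis: log2 signal minus the 75th percentile of the array; horizontal axis: group; points: arrays; bars: mean ± SD, n = 3). Dcn, Col1a1, Pdgfra, Lama4, Fst and Dkk2 lay higher on each re-isolated array than on each satellite array, Chrdl2, Fgfr4, Heyl and Des lower, and Pax7 differed between the 3 satellite arrays, with a level of −0.66 in replicate 3. Fst and Dkk2 were not well above background on any satellite array.

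The same question was asked of the iPax7 line. Dkk2 rose at least 370-fold, to 3.35 ± 0.41 (SD, n = 3; adjusted p = 0.00199), Fst at least 470-fold, to 3.7 ± 0.56 (adjusted p = 0.00114), and the matrix gene Dcn by 8.83 ± 0.75 log2 units (adjusted p = 0.00199). Over the alternatives, the rises of Dkk2 and Fst in iPax7 cells were as small as 5.76 and 6.13 log2 units. The transcription factor gene Ebf1 rose at least 252-fold by the probe used, to 2.8 ± 0.22 (adjusted p = 0.00199), while by any probe it was above background on 1 satellite array. Chrdl2 fell by 9.04 on the log2 scale (adjusted p = 0.00199), and the muscle ankyrin repeat gene Ankrd1 fell by 7.91 (adjusted p = 0.0217; measured on 1 iPax7 array).

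Other large rises in iPax7 cells were Aspn (at least 286-fold), Sfrp1 (9.67 ± 1.19, above background on 1 satellite array), Adamtsl3 (8.9 ± 0.69, on 1 satellite array), Col14a1 (8.83 ± 0.73, on 2 satellite arrays), the cell-surface glypican gene Gpc3 (8.83 ± 1.12, on 1 satellite array) and Naalad2 (at least 149-fold), with adjusted p between 0.00199 and 0.0158. Falls with adjusted p between 0.0167 and 0.0454 included Hmgxb3 (at least 207-fold), Erfe (−8.41 ± 1.26, measured on 1 iPax7 array), Mpv17l2 (−7.17 ± 1.22, on 2), Slc22a3 (at least 33.3-fold), Pitpnc1 (−6.8 ± 1.16, on 2), Atf7ip (−6.77 ± 0.94, on 2) and the sterol demethylase gene Cyp51 (−6.56 ± 0.97, on 1). By any probe, Sfrp1 and Adamtsl3 were above background on 3 satellite arrays, Pitpnc1 and Atf7ip on 3 iPax7 arrays and Cyp51 on 2. With both lines combined, 3 other probes of Pitpnc1 had the opposite sign to the probe used, as had 2 of Cyp51 and 1 of Atf7ip. Over probes above background on all 9 arrays the difference of Pitpnc1 was 0.21, and in the deposited value table that of Cyp51 was 2.17. The calls of Dkk2, Fst, Aspn, Ebf1, Adamtsl3, Col14a1, Dcn and Chrdl2 held whichever array was left out, and those of Mpv17l2 and Pitpnc1 held in 1 of 9 such fits. Those of Erfe and Atf7ip held in 4, those of Hmgxb3, Slc22a3, Cyp51 and Gpc3 in 5, those of Naalad2 and Ankrd1 in 6 and that of Sfrp1 in 7. Over probes above background on all 9 arrays Adamtsl3 differed by 1.6 and Sfrp1 by 3.14, and with the mean of a gene's probes Pitpnc1 differed by −1.15, Atf7ip by −1.76 and Cyp51 by −0.32, all without a call.

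Of the fibrillar matrix genes, 21 of 23 were higher in iPax7 cells, with a median of 3.57; 5 passed, among them Postn (7.29 ± 0.75), Col1a1 (6.27 ± 0.75) and Col1a2 (5.99 ± 0.74), and 16 passed adjusted over the list alone (camera adjusted p = 9.46e-18; adjusted p = 0.0201 with an estimated correlation). Fibroblast markers had a median of 2.18, with Pdgfra (8 ± 0.79), the progenitor surface marker gene Ly6a (5.17 ± 0.73), Dcn and Col1a1 higher, 20 not passing and 11 passing over the list alone (camera adjusted p = 8.39e-12; adjusted p = 0.0201 with an estimated correlation). With 1 array left out, the calls of Dcn, Pdgfra and Postn held in 9 of 9 fits, that of Col1a1 in 8, that of Col1a2 in 6 and that of Ly6a in 5. Basement membrane genes had a median of 2, or 1.76 with members at their bounds. Lama4 (8.33 ± 0.82) rose, 15 did not pass, and 5 were higher and 1 lower over the list alone (camera adjusted p = 0.00614; adjusted p = 0.194 with an estimated correlation). Over probes above background on all 9 arrays this call was lost (median 0.51, adjusted p = 0.0966). Interferon response genes had a median of 0.72 with 0 of 24 called and 1 over the list alone, Iigp1 (5.45 ± 0.96, adjusted p = 0.0501) being nearest to the threshold (camera adjusted p = 0.048; adjusted p = 0.194 with an estimated correlation). Wnt genes had a median of 0.21, and Dkk2, Sfrp1 and Sfrp2 (at least 156-fold, adjusted p = 0.0339, called in 2 of 9 fits with 1 array left out), all known as secreted modulators, rose among 27 members, with 5 over the list alone (camera adjusted p = 0.0494; adjusted p = 0.49 with an estimated correlation).

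Quiescence markers had a median of −1.99 in iPax7 cells, beside a rise of the fibroblast markers by a median of 2.18. Chrdl2 fell, 26 members did not pass, and 9 were lower and 4 higher over the list alone (camera adjusted p = 0.00614; adjusted p = 0.231 with an estimated correlation). Of its members the Notch target gene Heyl differed by −3.47 ± 0.71 (adjusted p = 0.0882) and the cell cycle inhibitor gene Cdkn1c by 3.84 ± 0.72 (adjusted p = 0.0641). Developmental sarcomere genes had a median of −0.49, with Ankrd1 lower, 14 not passing and 2 lower over the list alone (camera adjusted p = 0.0342; adjusted p = 0.194 with an estimated correlation). Genes of regional muscle identity had a median of −1.28 with 0 of 9 called on either count (camera adjusted p = 0.0223; adjusted p = 0.194 with an estimated correlation). Schwann and neural markers had a median of −0.9 with 0 of 17 called and 1 lower over the list alone (camera adjusted p = 0.035; adjusted p = 0.49 with an estimated correlation). Ribosomal protein genes had a median of −0.54 with 28 of 36 lower and 0 called on either count (camera adjusted p = 0.0494; adjusted p = 0.896 with an estimated correlation). The call was kept in 3 of 15 alternatives; quantile normalisation (adjusted p = 0.639) and the deposited values (0.545) were among the 12 that ended it. Of the other lists in iPax7 cells, interferon and Wnt genes kept their calls in 8 of 15 alternatives and Schwann and neural markers in 9.

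Several of these list calls in iPax7 cells rested on single arrays, and values in parentheses are camera adjusted p without the array named. The call of quiescence markers was lost without satellite replicate 1 (0.239). That of developmental sarcomere genes was lost without iPax7 replicate 1 (0.054) or 2 (0.0504) or satellite replicate 1 (0.0875) or 2 (0.0617), and that of regional identity genes without iPax7 replicate 1 (0.0514) or 2 (0.0504) or satellite replicate 2 (0.121). For Schwann and neural markers it was lost without iPax7 replicate 2 (0.141) or 3 (0.0595) or satellite replicate 2 (0.0687) or 3 (0.111). Interferon genes lost theirs without iPax3 replicate 1 (0.0549), iPax7 replicate 2 (0.251) or 3 (0.0971) or satellite replicate 2 (0.121) or 3 (0.0846). Wnt genes lost theirs without iPax3 replicate 1 (0.0549), iPax7 replicate 1 (0.054) or 2 (0.138) or satellite replicate 1 (0.251, median −0.38) or 2 (0.0617). Ribosomal genes lost theirs without iPax3 replicate 1, 2 or 3 (0.0549, 0.0503 and 0.0527), iPax7 replicate 2 (0.449) or 3 (0.156), or satellite replicate 1 (0.0852) or 3 (0.309). The calls of fibrillar matrix, fibroblast and basement membrane genes held in all 9 fits.

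**Figure D3:**
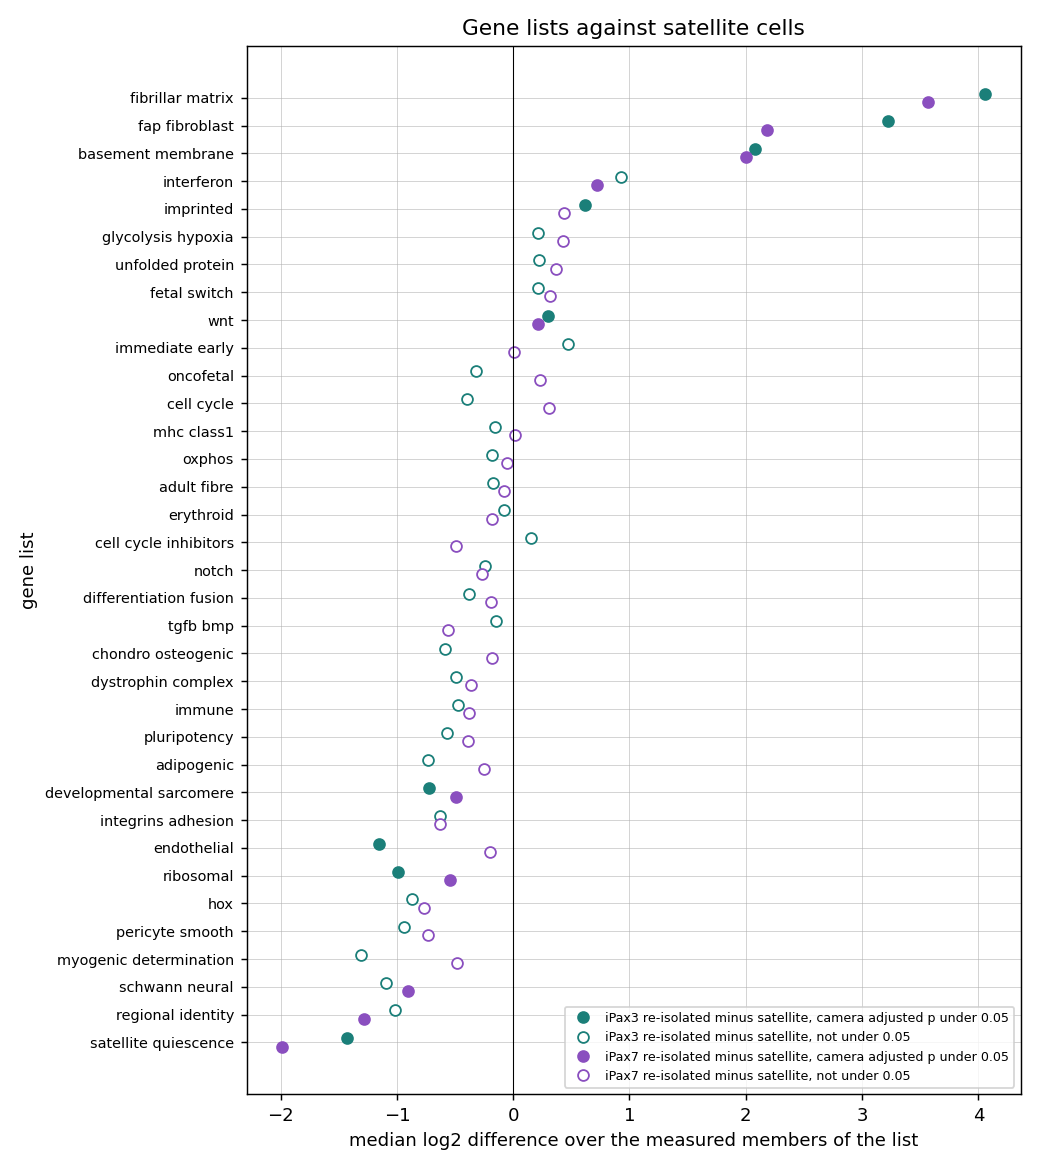
Median log2 difference from satellite cells over the measured members of each of the 35 gene lists (horizontal axis: log2; vertical axis: list; colours: line; filled points: camera adjusted p under 0.05 at a preset correlation of 0.01). Fibrillar matrix (4.06 in iPax3 and 3.57 in iPax7 cells) and fibroblast markers (3.22 and 2.18) lay highest, and quiescence markers (−1.43 and −1.99) lowest. With an estimated correlation 2 lists passed in each line.

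In iPax7 against satellite cells 121 genes were called, 99 higher and 22 lower (81.8% higher), with a smallest called difference of 4.06; 2818 genes had an unadjusted p under 0.05 against 1135 expected, and in 3705 (16.3%) the groups did not overlap, where chance gives 10%. The median over all genes was −0.153. The count was 77 without iPax3 replicate 2, 35, 58 and 41 without iPax7 replicate 1, 2 or 3, and 490, 47 and 62 without satellite replicate 1, 2 or 3. It was 43 with the slide and 36 with the scan day as a random block.

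Both lines shared much of their difference from satellite cells, though they also shared the control arrays. Higher in both were 60 genes, Fst, Dkk2, Dcn, Col1a1 and Pdgfra among them, and 12 were lower in both, with Chrdl2 and Ankrd1 among them; 0 were called in opposite directions, 26 genes were called in iPax3 alone and 49 in iPax7 alone. Simulated unchanged groups against the same controls gave 0 shared calls. With no difference to be called, that count was largely fixed in advance. It does not tell how many calls differing lines would share through the controls. Independent lists of these sizes would share 0.36 higher and 0.016 lower genes. Log2 differences of the lines correlated across genes at r = 0.731, against 0.501 in simulation (range 0.48 to 0.516 over 100 draws), with a covariance of 2.47 against 1, a difference of 1.47; 77.5% of genes had the same sign, against 66.6%. The simulated r is what groups of equal spread would give. The mean r within satellite cells was 0.64, against 0.73 within iPax3 and 0.68 within iPax7. A wider spread of the shared controls would raise r and covariance without any shared change, so the excess may be overstated. The 3 controls cannot be split into groups of 2, so part of the excess may come from the shared arrays. The 72 shared calls became 22, 27 and 19 without iPax3 replicate 1, 2 or 3, 32, 39 and 34 without iPax7 replicate 1, 2 or 3, 345, 29 and 36 without satellite replicate 1, 2 or 3, and 13 and 25 with the slide or the scan day as a random block.

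Taking both re-isolated groups together against satellite cells, 6 arrays against 3, brought further muscle genes past the threshold. Des, the muscle intermediate filament gene, fell by 3.66 on the log2 scale (± 0.66, adjusted p = 0.0416). The quiescence markers Bmp6 (−3.65 ± 0.64, adjusted p = 0.036), Heyl (−3.23 ± 0.62, adjusted p = 0.0486) and Fgfr4 (−3.03 ± 0.57, adjusted p = 0.0469) fell with Chrdl2 (−9.12 ± 0.6, adjusted p = 0.000624), while Col15a1 rose (4.25 ± 0.58, adjusted p = 0.0124). The homeobox gene Meox2 of limb muscle development rose by 6.58 ± 1.22 (adjusted p = 0.0436, above background on 1 satellite array). The myogenic factor gene Myod1 differed by −1.72 ± 0.57 (adjusted p = 0.217). Leaving out single arrays kept the calls of Bmp6, Des and Meox2 in 1 of 9 fits, that of Fgfr4 in 2 and that of Heyl in 0.

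Of 27 quiescence markers, 4 fell, 1 rose and 22 did not pass, with 10 lower and 3 higher adjusted over the list alone (median −1.68, camera adjusted p = 0.00305; adjusted p = 0.212 with an estimated correlation), and without satellite replicate 1 the list did not pass (adjusted p = 0.219). Of the 27 markers, 19 are also in another list. Per array, the median level of the quiescence markers was 0.79, 0.79 and 0.9 in iPax3 and 0.74, 0.32 and 0.35 in iPax7 cells. In satellite cells this median level was 2.51, 2.94 and 0.14. That of the fibroblast markers was 3.02, 2.61 and 3.26, then 4.15, 3.4 and 2.45, and in satellite cells 0.46, 0.1 and −0.04. Of the fibroblast markers, 9 of 24 rose, with 15 over the list alone (median 2.89, or 2.53 with members at their bounds; camera adjusted p = 5.34e-13; adjusted p = 0.0155 with an estimated correlation). Of the fibrillar matrix genes 10 of 23 rose, with 17 over the list alone (median 3.77, camera adjusted p = 1.79e-18; adjusted p = 0.0155 with an estimated correlation). These were the only lists whose calls held with an estimated correlation in any comparison. Of 16 basement membrane genes, Lama4 (8.02 ± 0.71), Lamb1 (6.08 ± 0.99), Nid1 (6.19 ± 1.1) and Col15a1 rose, and 6 were higher and 1 lower over the list alone (median 1.96, camera adjusted p = 0.000729; adjusted p = 0.161 with an estimated correlation). With 1 array left out, the calls of Lamb1 and Nid1 held in 1 of 9 fits, that of Col15a1 in 7 and that of Lama4 in 9.

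Signalling genes moved both ways. Of 27 TGF-beta and BMP genes, Fst (at least 443-fold) and Bmp5 (8.65 ± 0.65) were among 3 that rose, and the antagonist gene Chrdl2 and the ligand gene Bmp6 fell; 4 were higher and 3 lower over the list alone. The list did not shift against other genes (median −0.21, mean 0.34, camera adjusted p = 0.966). Over probes above background on all 9 arrays, Bmp5 differed by 2.03 and Sfrp1 by 4.33, both without a call; by any probe these genes were above background on 3 satellite arrays, and by the probe used on 1. Of 27 Wnt genes, Dkk2 (at least 277-fold), Sfrp1 (9.46 ± 1.03) and Sfrp2 (at least 87.2-fold, called in 4 of 9 fits with 1 array left out) rose, and 7 were higher over the list alone (median 0.25, camera adjusted p = 0.0224; adjusted p = 0.355 with an estimated correlation). Without iPax3 replicate 3 (0.0645) or satellite replicate 1 (0.156, median −0.41), or over probes above background on all 9 arrays (0.53, median −0.27), the list did not pass.

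Smaller list shifts accompanied these. Imprinted genes had a median of 0.84, with Igf2, the fetal growth factor gene (9.49 ± 1.81, adjusted p = 0.0488, above background on 1 satellite array by the probe used and on 3 by any probe), and Dcn higher, 30 not passing and 4 over the list alone (camera adjusted p = 0.0294; adjusted p = 0.161 with an estimated correlation). Interferon genes had a median of 0.6, with Iigp1 (4.51 ± 0.83, on 2 satellite arrays) higher, 23 not passing and 1 over the list alone (camera adjusted p = 0.0345; adjusted p = 0.201 with an estimated correlation). Developmental sarcomere genes had a median of −0.66, with Ankrd1 (−7.6 ± 0.98) lower, 14 not passing, Csrp3 (−4.7 ± 0.98, adjusted p = 0.0675) among them, and 2 lower over the list alone (camera adjusted p = 0.0224; adjusted p = 0.161 with an estimated correlation). Regional identity genes had a median of −1.12 with 0 of 9 called and 3 lower over the list alone. Pitx3 differed by −2.67 ± 0.68 (adjusted p = 0.123) (camera adjusted p = 0.0307; adjusted p = 0.212 with an estimated correlation). Schwann and neural markers had a median of −0.97 with 0 of 17 called and 1 lower over the list alone, Map2 (−5.89 ± 1.39, adjusted p = 0.0994) being nearest to the threshold (camera adjusted p = 0.0294; adjusted p = 0.466 with an estimated correlation). Ribosomal protein genes had a median of −0.83 with 0 of 36 called on either count (camera adjusted p = 0.00305; adjusted p = 0.677 with an estimated correlation), and −0.26 under quantile normalisation (adjusted p = 0.305).

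Left-out arrays ended several of these smaller calls of both lines, with camera adjusted p in parentheses. The calls of Igf2 and Iigp1 themselves held in 1 of 9 such fits, and those of Dcn and Ankrd1 in 9. Imprinted genes, Igf2 and Dcn included, did not pass without iPax3 replicate 3 (0.0671), iPax7 replicate 2 (0.0596) or satellite replicate 3 (0.0809). Interferon genes did not pass without iPax3 replicate 1 (0.0684) or 3 (0.0856), iPax7 replicate 2 (0.089) or 3 (0.0533), or satellite replicate 2 (0.128) or 3 (0.0739). Developmental sarcomere genes did not pass without satellite replicate 1 (0.0891), and regional identity genes not without iPax7 replicate 1 (0.0533) or satellite replicate 1 (0.0891) or 2 (0.237). Schwann and neural markers did not pass without iPax7 replicate 2 (0.0596) or satellite replicate 2 (0.0703) or 3 (0.087). Of 14 alternatives, 11 kept the call of Schwann and neural markers and 12 those of interferon, regional identity and ribosomal genes. That of developmental sarcomere genes was kept in 13 and that of imprinted genes in 14.

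In all, 236 genes differed between both re-isolated groups and satellite cells, 182 higher and 54 lower (77.1% higher); 3491 had an unadjusted p under 0.05 against 1135 expected, and in 1896 (8.35%) the groups did not overlap, where chance gives 2.38%. The median over all genes was −0.156, and with normexp 267 genes were called, 62.5% of them higher. The count was 108, 118 and 109 without iPax3 replicate 1, 2 or 3, 112 and 130 without iPax7 replicate 2 or 3, and 692, 75 and 85 without satellite replicate 1, 2 or 3. It was 46 with the slide and 43 with the scan day as a random block.

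The last comparison set the iPax7 against the iPax3 line. No single gene passed the test in the main fit, where limma called 0 of 22705 genes and the smallest adjusted p was 0.066. An unadjusted p under 0.05 was found for 931 genes, against 1135 expected by chance. Groups did not overlap in 2111 genes (9.3%), where chance gives 10%. Pax7 differed by −1.24 ± 1.21 (adjusted p = 1) and Pax3 by 0.46 ± 1.12 (adjusted p = 1). Fibrillar matrix genes (median −0.01, camera adjusted p = 0.911), fibroblast markers (0.1, 0.969) and quiescence markers (−0.19, 0.911) did not pass, with 0, 0 and 1 of their members called over the list alone. The median standard error was 1.04 log2 units, so differences of a few log2 units could go undetected.

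Endothelial markers rose as a list in iPax7 against iPax3 cells, with 15 of 20 higher, a median of 1.02 and 0 members called, or 3 over the list alone (camera adjusted p = 0.00316; adjusted p = 0.184 with an estimated correlation; fry adjusted p = 0.0252). The angiopoietin receptor gene Tek was at least 140-fold above its level in iPax3 cells by the probe used (adjusted p = 0.71), which was above background on none of their arrays, while by any probe the gene was on 1. The tight junction gene Cldn5 differed by 3.54 ± 0.85 (adjusted p = 0.809), the lymphatic marker gene Lyve1 by 4.95 ± 1.24 (adjusted p = 0.829, above background on 1 iPax3 array by the probe used and on 3 by any probe) and Ly6c1 by 2.08 ± 0.87 (adjusted p = 1). The list shares Tek with the quiescence markers, Ly6c1 with the fibroblast markers and Fabp4 with the adipogenic markers. With the slide as a fixed block, and likewise within slide 1, the median was 0.15. Both values compare 3 iPax3 arrays with iPax7 replicate 1 alone, so they cannot tell the slide from that array. It had the smallest share of probes well above background (56.6%). Without iPax7 replicate 2 the list did not pass (adjusted p = 0.0592), and neither did it over probes above background on all 9 arrays (0.45).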

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

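The test of the slide was chosen after the result was seen. A difference between groups drew attention to endothelial markers, higher as a list in iPax7 than in iPax3 cells (median 1.02, camera adjusted p = 0.00316; adjusted p = 0.184 with an estimated correlation), while 0 single genes were called between these lines. Their median level was −2.09, −2.69 and −2.47 in iPax3 replicates 1 to 3, −2.92, −1.29 and −1.37 in iPax7 replicates 1 to 3, and 0.06, −1.54 and −1 in the satellite replicates. The probe used for Tek, not above background on any iPax3 array and on 1 satellite array, read −5.79, −6.34 and −7.61 in iPax3 cells, 3.25, 1.88 and 0.63 in iPax7 cells and 1.05, −6.31 and −6.8 in satellite cells. The difference might come from the slide or from endothelial cells in the sort, whose gate the labels do not give. With the slide as a fixed block the median was 0.15, but that contrast rests on iPax7 replicate 1 alone. It cannot tell the slide from that array. The lowest camera adjusted p over all alternatives was 3.87e-05. The call was kept in 12 of 14 alternatives and in 8 of 9 fits with 1 array left out. Of the 20 markers, 14 were above background on all satellite arrays and 3 are also in another list.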

How the results depend on the processing

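Counts of called genes depended strongly on the processing, and for most changes the cause was not tested. For iPax3 against satellite cells (98 genes) the count was 181 in the deposited value table, 170 with probes above background on all arrays of a group, 56 with only the arrays compared, 233 with array weights, 37 with the replicate number as a block, 14 with the slide and 27 with the scan day as a random block, and 19 to 451 with 1 array left out. For iPax7 against satellite cells (121) the count was 189 in the deposited table, 191 with probes above background on all arrays of a group, 38 with only the arrays compared, 55 with the replicate block, 43 with the slide, 36 with the scan day, 76 over probes above background on all 9 arrays and 35 to 490 with 1 array left out. For both groups together (236) the count was 115 with the replicate block, 46 with the slide, 43 with the scan day and 75 to 692 with 1 array left out. Between iPax7 and iPax3 (0) it was 1 with quantile normalisation, with probes above background on all arrays of a group, with the mean of a gene's probes and with array weights. The shared calls (72) became 119 in the deposited table, 109 with probes above background on all arrays of a group, 43 over probes above background on all 9 arrays, 31 with the replicate block, 13 with the slide, 25 with the scan day and 19 to 345 with 1 array left out. Lists called in iPax3 cells (9) fell to 5 over probes above background on all 9 arrays, to 2 with an estimated correlation and ranged from 5 to 10 with 1 array left out. In iPax7 cells (10) they were 6 without a filter on dim probes, 4 over probes above background on all 9 arrays, 5 with the mean of a gene's probes, 2 with an estimated correlation and 4 to 9 with 1 array left out. Between iPax7 and iPax3 (1) they were 0 over probes above background on all 9 arrays, 2 with array weights, 0 with an estimated correlation and 0 to 2 with 1 array left out, and for both groups (11) they were 6 over probes above background on all 9 arrays, 2 with an estimated correlation and 7 to 11 with 1 array left out. The mean correlation between the re-isolated arrays of both lines and the satellite arrays (0.61) was 0.71 without a filter on dim probes. Of the named called genes, 2 changed sign, both in iPax7 against satellite cells: Pitpnc1 was 0.21 over probes above background on all 9 arrays and Cyp51 2.17 in the deposited table. Raising low signals to the detection floor, chosen after the data were seen, gave 99, 130, 0 and 249 called genes. Replicate numbers did not pair samples: same-numbered arrays of different groups had a mean r of −0.02 after group means were removed. The calls of the fibrillar matrix and fibroblast genes as lists held under all alternatives. Those of single members did not all hold: of 15 alternatives, 10 kept Serpinf1 and 11 Col1a2 in iPax3 cells, and 11 Ly6a in iPax7 cells. Fst, Dkk2, Dcn and Chrdl2 kept their calls whichever array was left out. Low signal limits the test of genes near background, such as Pax3.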

Other observations

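Gene groups that did not pass camera as lists held some genes that changed in both re-isolated groups against satellite cells. With fry, myogenic determination genes and pericyte and smooth muscle markers were lower as lists, at a fry adjusted p of 0.0357 and 0.00268. Values in parentheses are the median log2 difference and the camera adjusted p. Myogenic determination genes (−0.75, 0.351) held Meox2, which rose, and 16 that did not pass, Myf6 (−2.69 ± 0.59, adjusted p = 0.0783) among them; 1 was higher and 2 lower over the list alone. Differentiation and fusion genes (−0.45, 0.399) held Des, which fell, and 17 that did not pass. Over the list alone 1 was higher and 3 lower. Cdh15, which is in the quiescence and the adhesion lists, did not pass (−4.25 ± 0.93, adjusted p = 0.0764). Pericyte and smooth muscle markers (−0.41, 0.351) held the smooth muscle myosin gene Myh11 (−2.95 ± 0.56, adjusted p = 0.0482) and Des, both lower. Notch genes (−0.35, 0.628) held Heyl and fetal switch genes (0.25, 0.966) Fgfr4, both lower; oncofetal genes (0.11, 0.423) held Igf2 and cartilage and bone genes (−0.17, 0.966) Col2a1 (4.33 ± 0.66, adjusted p = 0.0213), both higher. With 1 array left out, the calls of Meox2, Des, Myh11 and Igf2 held in 1 of 9 fits, those of Fgfr4 and Col2a1 in 2 and that of Heyl in 0. Of 14 alternatives 8 kept the call of Igf2 and 10 that of Col2a1, which differed by 1.02 with the mean of its probes. Adult fibre genes (−0.09, 0.966), the dystrophin complex (−0.35, 0.933), pluripotency markers (−0.51, 0.401) and cell cycle genes (−0.15, 0.954) held 0 called genes on either count.

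Further lists held 0 called genes over all genes. These were cell cycle inhibitors (−0.04, 0.684), with Cdkn1c at 3.07 ± 0.62 (adjusted p = 0.0617), immediate early genes (0.28, 0.737), integrins and adhesion (−0.55, 0.505), MHC class I (−0.44, 0.954), Hox genes (−0.74, 0.178), with Hoxb2 at 3.02 ± 0.62 (adjusted p = 0.0627), immune (−0.58, 0.907), endothelial (−0.84, 0.351), erythroid (−0.2, 0.688) and adipogenic markers (−0.67, 0.954), respiratory chain (0.06, 0.966), glycolysis and hypoxia (0.39, 0.459) and unfolded protein genes (0.24, 0.407). Adjusted over the list alone, 2 integrin and adhesion genes were higher and 4 lower, and 1 Hox gene was higher and 1 lower. Likewise 1 member was higher in each of the cell cycle inhibitor, immune, endothelial and adipogenic lists. In each of the immediate early and MHC class I lists 1 was lower. Mean and median differed in sign for cell cycle inhibitors (mean 0.66), immune (0.07), erythroid (0.6), adult fibre (0.1), cartilage and bone (0.09), fetal switch (−0.06) and TGF-beta and BMP genes (0.34). The test direction of respiratory chain genes was opposite to their median. Of the sex-linked genes 3 of 5 were measured: Xist differed by 0.99 (adjusted p = 0.648), Ddx3y by −4.77 (adjusted p = 0.187) and Uty by −3.99 (adjusted p = 0.204). Of 7 probes of Y-linked genes, 5, 2 and 2 were above background in satellite replicates 1 to 3. In iPax3 replicates 1 to 3 there were 0, 1 and 2, and in the iPax7 replicates 0, 2 and 0. A difference in sex between the groups was not tested, and these values do not settle it.

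The slide and scan day test was chosen after the result was seen. Fibroblast and matrix genes were higher in both re-isolated groups, and RNA from fibroblast-type cells in the re-isolated sort, whose gate the labels do not give, may be a source: a second list of 36 fibroblast genes, 1 of them in the fixed lists, had a median of 2.27, with 32 higher (camera p = 1.47e-12; p = 0.00625 with an estimated correlation). Expression by the transplanted myogenic cells could give the same values, and the data hold 0 values per single cell. Such genes also gave signal on the satellite arrays, with 20 of 24 fibroblast markers above background on all of them. Bulk RNA does not tell whether that signal came from satellite cells or from other cells in their sort. Of the 24 markers, 6 are also in another list. Dcn read 7.4 and 7.64 in iPax3 and iPax7 cells and −1.19 in satellite cells. Scaling was excluded as the whole cause, as the smallest median of the fibroblast list over other scalings was 2.58, while slide and scan day could not be told apart from cell type, with a difference of 0.43 between satellite arrays of different days.

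The dilution and scaling tests of the quiescence markers were chosen after the result was seen. In both re-isolated groups the list had a median of −1.68, but 22 of 27 members did not pass, the list did not pass with an estimated correlation (adjusted p = 0.212) or without satellite replicate 1 (0.219), and over its alternatives with the preset correlation the adjusted p ranged from 4.29e-05 to 0.219. Satellite replicate 3, at a median level of 0.14, lay below each re-isolated array (0.32 to 0.9). Fewer myogenic cells in the sort might lower such a list, and this stays open: of 27 members 6 fell more than Myod1 by over 2 standard errors, 6 fell less or rose and 15 lay within 2 standard errors. Scaling was excluded as the whole cause, as the median over the other scalings was −1.45 or lower and the list passed under each (adjusted p 0.000738 to 0.00663); strain, slide, scan day and a change of the cells themselves were not separable.

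All 3 tests of satellite replicate 1 were chosen after the result was seen. Its mean r with the re-isolated arrays exceeded that of satellite replicates 2 and 3 by 0.092 over 22563 genes. More probes above background might raise it, yet over 13594 genes above background on all 9 arrays the gap was 0.121. Genes below background on some arrays therefore did not make the gap. The 75th percentile of the signal was 849 on satellite replicate 1, against 353.9 and 206.5 on replicates 2 and 3. An effect of that stronger signal was not tested. Fibroblast RNA in that array stays open, as its fibroblast list median lay 0.43 above the mean of those of the others. It was the only array, 1 of 9, of its scan day, so that a scan effect could not be told from the sample, and beyond fibroblast RNA no biological explanation was tested.

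The splits of the arrays were fixed before the data were examined. For both groups against satellite cells, in a fit with only 2 groups, the real grouping called 341 genes. Of 84 splits 1, the real one, called as many, and the highest other count was 259. That split set apart iPax7 replicate 1 and satellite replicates 2 and 3. These arrays had the smallest shares of probes well above background (56.6%, 57% and 60.4%). For iPax3 against satellite cells 10 splits are too few for a share under 0.05; the real grouping called 56 genes and the highest other 0, with 1 split as large. For iPax7 against satellite cells, with 10 splits again, the real grouping called 38 genes and another split, iPax7 replicate 1 with satellite replicates 2 and 3, called 58, so that 2 splits called as many. Between iPax7 and iPax3 all 10 splits called 0 genes.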
